A study of Homo sapiens with 4 samples.

How the data were processed

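RNA was measured in 4 libraries from NCI-H460, an established human non-small cell lung cancer line. Per the labels' protocols, cells received 0 or 4 Gy of gamma radiation and were then kept for 48 h with 2 uM 3-deazaneplanocin A (DZNep) or with its solvent DMSO. Total RNA was extracted with Trizol and made into libraries with the Lexogen SENSE mRNA kit, per the labels' protocols. The groups were DMSO 0 Gy, DMSO 4 Gy, DZNep 0 Gy and DZNep 4 Gy, with 1 library each.

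The authors deposited raw counts per gene symbol, 1 table per library, with no normalization. Per the submitters' processing notes, TopHat, edgeR and the hg19 build were used. Their versions, the counting program, the annotation and the use of strand are not given in the sources used here. The tables held 26364 gene symbols, of which 4250 had no count in any library. Totals were 136594350 counts for DMSO 0 Gy, 112461380 for DMSO 4 Gy, 128255695 for DZNep 0 Gy and 116234177 for DZNep 4 Gy. Among counts of 1 to 59, even values made up 55.9% to 58.1% per library, so some tags may be mates of 1 fragment counted separately. Counting intervals are then too narrow. The reference at hand was GENCODE on another build than hg19, so it gave gene length and GC content by symbol and no coordinates.

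Counts were scaled with edgeR 4.0.16 (R 4.3.3) by the TMM method, with factors of 0.979 to 1.01. Genes at 1 CPM (counts scaled by library size) or more in at least 2 libraries were tested, which left 13378. Symbols of short RNAs (347 of those) stayed in the test and were not named, since a poly(A) library cannot measure them apart from their host genes. With 1 library per group, no difference between 2 libraries has a replicate check, and none was tested. The DZNep effect and the radiation effect were each tested over all 4 libraries in an additive model of drug and dose, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at an adjusted p of 0.05. That model has 1 residual degree of freedom, moderated with 11.5 prior degrees of freedom, and a common biological coefficient of variation of 0.163. Its p-values measure the spread between these 4 libraries, which nothing shows to be independent cultures, and any departure from additivity counts as spread. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic.

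For 2 libraries, log2 ratios of TMM-scaled CPM were taken with a prior count of 2, and genes at least 2-fold apart were counted among those at 10 CPM or more in the higher library. Intervals of these ratios are exact conditional binomial 95% intervals without the prior count and cover counting error only. The interaction is the difference between the radiation ratio in DZNep and that in DMSO and has no error estimate. A count of 0 would allow up to 3 counts, which is 0.0217 to 0.0267 CPM.

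Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. Named genes were the 12 largest rises and 12 largest falls of each effect among genes past the threshold, with the same direction in both pairs and 10 CPM or more in at least 1 library. To these were added the 5 highest and 5 lowest ratios of each 2-library comparison and of the interaction at 10 CPM or more, and up to 4 members per list with the largest absolute effect. AHCY, EZH2, TXNIP, CDKN1A, MDM2 and GDF15 were always named. Some genes that this rule names are not reported here. For each list, members past the threshold were counted over all tested genes and adjusted over the list alone. List medians were set beside 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. In a scan of 41 gene families by symbol, made after the data were examined, 60 of 123 family medians lay outside the middle 95% of random lists, against 6.15 expected by chance. Related genes move together, so such a range is weak evidence about any list.

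The test was run on simulated data for the DZNep effect over 13378 genes, where it recovered 80% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 9 false calls among 189. With no simulated radiation effect it made 0 calls, and 4.84% of genes had an unadjusted p under 0.05. Changed genes were drawn from those at a mean of 10 CPM or more. Counts were drawn at the common coefficient of variation, with no interaction and no difference between cultures. These figures are therefore not the error rates of the test on the real libraries. In simulated lists of 30 genes, 3% of 100 unshifted lists lay outside the middle 95% of random lists, and 100% of 50 lists shifted by 0.3 lay above it. Trends with GC content and gene length were removed with mgcv 1.9.3. On simulated data over 13378 genes, that correction took a trend-only list median from 0.48 to -0.03 and kept 0.43 of a true shift of 0.5.

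Alternatives were DESeq2 1.42.0, RLE and plain library size scaling, no filter, a 10 CPM filter, a model without the other factor, an adjusted p of 0.01, a 2-fold minimum, prior counts of 0.25 and 5, minimums of 0 and 50 CPM, and thinning to the shallowest library. Binomial thinning of all counts to 50% and leaving out short RNA symbols were added after the data were examined. Leaving out a library was not possible, since 3 libraries leave the additive model with no residual degree of freedom. Figures were drawn with matplotlib 3.10.9.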

Results

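Messenger RNA was counted in NCI-H460 lung cancer cells that had received 0 or 4 Gy of gamma radiation and then DZNep or DMSO for 48 h. DZNep inhibits S-adenosylhomocysteine hydrolase, the product of AHCY, and thereby slows methylation by enzymes such as EZH2, the catalytic subunit of Polycomb repressive complex PRC2. The design asked which genes differ with the drug, with radiation, and with both. Each of the 4 groups was 1 library of 112461380 to 136594350 counts, so no group has a replicate. The 100 most abundant genes took 33.38% to 33.97% of the counts in each library. Across genes, log2(CPM + 1) correlated at 0.987 between the DZNep libraries, 0.981 between the DMSO libraries, 0.967 between the 0 Gy libraries and 0.968 between the 4 Gy libraries.

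DZNep was accompanied by rises of RASD1, a Ras-family GTPase, CITED2, a transcriptional co-regulator, TNS4, a focal adhesion protein, and FBXO32, a ubiquitin ligase subunit. It was also accompanied by falls of KMO, an enzyme of tryptophan breakdown, and MGMT, a DNA repair enzyme. RASD1 stood at 23.5 and 17.9 CPM in the DZNep libraries at 0 and 4 Gy and at 0.867 and 0.374 CPM in DMSO, a log2 fold change of 5.12 (SE 0.26, adjusted p = 6.47e-07). CITED2 stood at 945 and 1034 CPM with DZNep against 54.97 and 117 CPM (3.62, SE 0.21, adjusted p = 1.05e-06). TNS4 rose by 3.93 (SE 0.27), the receptor gene IL1RL1 by 3.81 (SE 0.29), NRAP by 3.61 (SE 0.30), CR1 by 3.47 (SE 0.75), IRF7 by 3.23 (SE 0.34) and the kinesin gene KIF21B by 3.18 (SE 0.26). ANKRD1 (3.17, SE 0.23), FRMD3 (3.16, SE 0.30), NUPR1 (3.03, SE 0.34) and FBXO32 (3.01, SE 0.24) completed the 12 largest rises at 10 CPM or more. MGMT stood at 1.33 and 0.844 CPM with DZNep against 8.93 and 10.9 CPM (-3.21, SE 0.29, adjusted p = 1.91e-05), and KMO fell by 3.29 (SE 0.21). The other large falls were LOC388282 (-4.60, SE 0.24), AKR1B15 (-3.88, SE 0.18), FAM19A5 (-3.55, SE 0.22), PCBP3 (-3.25, SE 0.18), ZSCAN31 (-3.21, SE 0.24), NKD2 (-3.10, SE 0.27), ACTA2-AS1 (-3.08, SE 0.32), CCDC92 (-3.06, SE 0.17), PDE9A (-3.05, SE 0.20) and LMF1 (-3.00, SE 0.21). CR1 had 985 and 1231 counts in the DZNep libraries at 0 and 4 Gy, 342 in DMSO 0 Gy and 16 in DMSO 4 Gy. Its ratio was 1.62 at 0 Gy and 6.09 at 4 Gy, so the size of its rise rests on 1 library. AKR1B15 is nearly identical to AKR1B10, CR1 has a close paralog, and ACTA2-AS1 lies antisense to ACTA2, so their counts are uncertain.

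In total, 1446 of 13378 tested genes rose and 1640 fell with DZNep, of which 553 and 693 changed at least 2-fold. The counts given for each list are to be read beside these shares. All 3086 had the same direction at 0 and 4 Gy, which the additive model favours, against 74.2% of all tested genes. Without dose in the model the counts were 355 and 366.

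Inflammatory genes, epithelial and mesenchymal markers, developmental regulators and stress response genes rose with DZNep more often than they fell. Of 31 measured NF-kB and secreted inflammatory factors, 18 rose and 1 fell (21 and 1 adjusted over the list alone). Among the rises were the collagenase gene MMP1 (2.68, SE 0.21), the chemokine gene CCL20 (2.44, SE 0.24), the growth factor gene AREG (1.82, SE 0.18) and the adhesion molecule gene ICAM1 (1.79, SE 0.18). The fall was that of LIF (-1.27, SE 0.17). The median of the list was 0.85, against -0.21 to 0.18 for the middle 95% of random lists, and 0.44 over the members that pass a 10 CPM filter. Of 29 epithelial and mesenchymal markers, 15 rose and 0 fell (17 and 2 adjusted over the list alone; median 0.55), including ANKRD1, KRT81 (1.75, SE 0.19) and KRT18 (1.58, SE 0.13). The list pools both kinds of marker with other genes such as ANKRD1, so its rise gives no direction between epithelial and mesenchymal. KRT81 closely resembles its neighbour KRT86, so its count is uncertain. Of 56 listed developmental regulators known as Polycomb targets, 29 were measured, and the rest were not among the tested genes. Of the 29, 13 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 0.56, and it was 0.46 over the members that enter without the filter on low counts. The rises were led at 10 CPM or more by TBX2 (1.30, SE 0.18), WNT5A (1.17, SE 0.17), PAX9 (1.16, SE 0.18) and TBX3 (0.83, SE 0.20). Of 30 genes of the integrated stress and unfolded protein responses, 12 rose and 2 fell (13 and 3 adjusted over the list alone; median 0.37), including ATF3 (1.85, SE 0.18), VLDLR (1.67, SE 0.17), CHAC1 (1.65, SE 0.17) and PSAT1 (1.05, SE 0.15), while HSP90B1 (-0.44, SE 0.15) and PDIA4 (-0.62, SE 0.15) fell.

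Of 40 cytosolic ribosomal protein genes, 0 rose, 13 fell and 27 did not pass the test (0 rises and 19 falls adjusted over the list alone; median -0.36, with -0.52 at 0 Gy and -0.17 at 4 Gy). The falls included RPS20 (-0.76, SE 0.15), RPS3 (-0.73, SE 0.15), RPLP1 (-0.70, SE 0.13) and RPL3 (-0.70, SE 0.13). Of 30 NRF2 targets, 2 rose and 8 fell (4 and 8 adjusted over the list alone). OSGIN1 (-1.74, SE 0.17), AKR1B10 (-1.64, SE 0.15) and ABCC3 (-0.95, SE 0.16) fell, while NQO1, a quinone reductase, rose (1.13, SE 0.13), as did ALDH3A1 (0.68, SE 0.14). Of 24 cholesterol synthesis genes, 3 fell (3 adjusted over the list alone), INSIG1 (-1.13, SE 0.22), LSS (-0.61, SE 0.17) and IDI1 (-1.39, SE 0.28). Of 28 hypoxia and glycolysis genes, 6 rose, NDRG1 by 2.33 (SE 0.16), and 4 fell, PFKP by 1.12 (SE 0.17); adjusted over the list alone, 9 and 4 did.

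AHCY (-0.33, SE 0.14, adjusted p = 0.117) and EZH2 (-0.26, SE 0.17, adjusted p = 0.293) did not pass the test. Of 28 Polycomb subunit genes, BMI1 (0.78, SE 0.19), JARID2 (0.76, SE 0.18), CBX2 (0.57, SE 0.19) and CBX6 (0.56, SE 0.17) rose and 0 fell (6 and 2 adjusted over the list alone). The median of that list was 0.06, inside the range of -0.20 to 0.18 for random lists. Of 31 methyltransferase genes only PRMT3 fell (-1.06, SE 0.18; 1 adjusted over the list alone), and of 20 histone demethylase and TET genes only KDM5B rose (0.73, SE 0.21; 0 adjusted over the list alone). Of 26 genes of methionine and polyamine metabolism, 4 rose and 4 fell (4 and 4 adjusted over the list alone), among them CTH (1.59, SE 0.22), SAT1 (1.49, SE 0.15) and PEMT (-1.65, SE 0.17). Of 9 measured genes linked to DZNep in earlier work, FBXO32 and KLF2 (1.26, SE 0.17) rose (3 and 1 adjusted over the list alone), and TXNIP (0.27, SE 0.16, adjusted p = 0.26) did not pass.

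The remaining lists held calls in both directions or few calls. With DZNep, 6 of 39 p53 targets rose and 6 fell (6 and 6 adjusted over the list alone): GDF15, a secreted growth factor, rose (2.02, SE 0.17), and SPATA18 (-1.34, SE 0.31), TP53INP1 (-1.10, SE 0.22) and CCNG1 (-1.08, SE 0.16) fell. Of 37 S phase genes 2 fell, CCNE2 (-1.18, SE 0.35) among them (0 adjusted over the list alone). Of 36 mitosis genes HMMR fell (-0.99, SE 0.17; 1 adjusted over the list alone). Of 40 double strand break repair genes 3 rose and 5 fell (2 and 1 adjusted over the list alone), with EXO1 at 0.75 (SE 0.15) and ATR at -1.28 (SE 0.27). In the interferon list 4 of 33 rose and 4 fell (4 and 5 adjusted over the list alone). IRF7 (3.23, SE 0.34) and IRF1 (1.31, SE 0.20) rose most, PARP9 fell by 0.60 (SE 0.18), and IFI44 (-1.504, SE 0.34) and IFI44L (-1.33, SE 0.31) fell most. Apoptosis genes gave 6 rises and 2 falls of 25 (6 and 2 adjusted over the list alone), with BCL2L1 at 1.05 (SE 0.16) and BID at -0.65 (SE 0.16). MYC and ribosome biogenesis genes gave 4 and 1 of 24 (4 and 1 adjusted over the list alone), with MYC at 0.68 (SE 0.14) and NPM1 at -0.69 (SE 0.12). Lysosome and autophagy genes gave 4 and 1 of 28 (1 and 0 adjusted over the list alone), antigen presentation genes 3 and 1 of 19 (4 and 1), histone genes 3 and 1 of 14 (3 and 1), neuroendocrine and lung lineage genes 1 and 0 of 7 (1 and 0), and germline genes 0 and 0 of 5 (0 and 0). CTSL (0.84, SE 0.13), CD274 (0.67, SE 0.17), H1F0 (1.30, SE 0.17) and NCAM1 (1.39, SE 0.16) were among these rises. Of 8 measured markers of fibroblasts, endothelium or blood, ACTA2 (-2.56, SE 0.30), COL1A1 (-0.54, SE 0.18) and COL3A1 (-0.74, SE 0.22) fell and 0 rose (0 and 3 adjusted over the list alone), and the list's median was -0.29, but 0.28 without the filter on low counts. LIF, HSP90B1, PDIA4, IDI1, CCNE2, ATR, IFI44, IFI44L and COL3A1 were named after their values were seen, as were XRCC4, BBC3 and STARD4 among the radiation calls.

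Library by library, DZNep and DMSO differed at least 2-fold for 294 genes in each direction at 0 Gy, and for 262 higher and 322 lower at 4 Gy. Across 8502 genes at 10 CPM or more the log2 ratios at 0 and 4 Gy correlated at r = 0.77 (rho = 0.70), with no library in common; genes are not independent replicates. At 0 Gy the highest ratios at 10 CPM or more were those of RASD1 (4.74, interval 4.50 to 5.04), TNS4 (4.49), NRAP (4.39), CITED2 (4.10) and IL1RL1 (4.07). The lowest were those of MYO1G (-4.51), LOC388282 (-4.37), AKR1B15 (-3.90), FAM19A5 (-3.90) and DLGAP1 (-3.57). At 4 Gy they were CR1 (6.09, interval 5.54 to 7.06), RASD1 (5.52), IRF7 (3.99), TNS4 (3.37) and KIF21B (3.25), and at the low end LOC388282 (-4.76), AKR1B15 (-3.85), ZSCAN31 (-3.68), MGMT (-3.67) and PDE9A (-3.37).

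**Figure D1:**
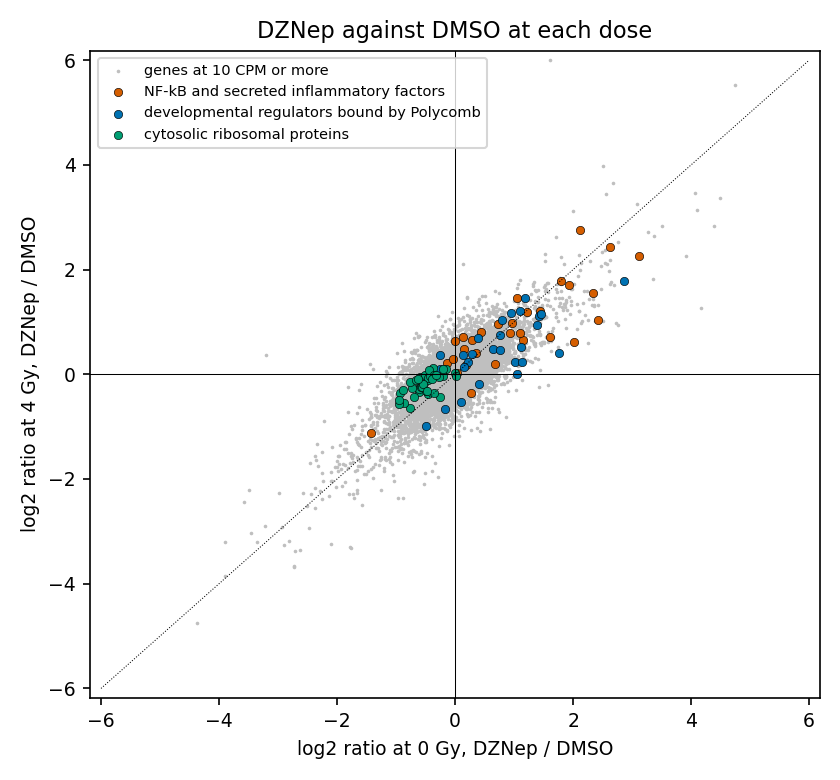
Log2 ratio of DZNep to DMSO at 0 Gy (x axis) and 4 Gy (y axis), 1 library against 1, with each grey point a gene at 10 CPM or more, colours marking 3 gene lists, the dotted line equality, and 1 gene beyond 6 drawn at the edge. The inflammatory list lies mostly above 0 on both axes (medians 0.92 and 0.72) and the ribosomal protein list mostly below (medians -0.52 and -0.17).

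Radiation was accompanied by rises of p53 targets and falls of S phase genes. CDKN1A, the inhibitor of cyclin-dependent kinases, stood at 1296 and 1307 CPM at 4 Gy with DMSO and DZNep, against 201 and 251 CPM at 0 Gy (2.53, SE 0.15, adjusted p = 4.96e-06). GDF15 stood at 64.7 and 304 CPM against 10.4 and 36.1 CPM (2.86, SE 0.17, adjusted p = 4.96e-06). PVT1, a long non-coding RNA gene, rose by 3.32 (SE 0.36, adjusted p = 0.000395). NLRP1 (2.88, SE 0.38), CEACAM1 (2.71, SE 0.51), BTG2 (2.68, SE 0.18), ACTA2-AS1 (2.48, SE 0.32), ANK1 (2.42, SE 0.27), TP53INP1 (2.31, SE 0.23), FDXR (2.19, SE 0.17), SPATA18 (2.15, SE 0.32) and ACTA2 (2.11, SE 0.29) also rose, as did TXNIP (1.57, SE 0.17) and MDM2, a ubiquitin ligase gene (1.60, SE 0.17, adjusted p = 0.000395). Among the falls were RRM2, a ribonucleotide reductase subunit (-1.21, SE 0.16, adjusted p = 0.00177), the uracil glycosylase gene UNG (-1.25, SE 0.20), the cyclin gene CCNA2 (-1.16, SE 0.21), and the replication genes CLSPN (-1.18, SE 0.22), POLE2 (-1.10, SE 0.18), GINS2 (-1.05, SE 0.19) and MCM6 (-1.03, SE 0.17). WDR76 (-1.30, SE 0.17), DNAJC25 (-1.28, SE 0.23), PASK (-1.18, SE 0.22), SYT7 (-1.12, SE 0.26) and INSIG1 (-1.04, SE 0.22) completed the 12 largest falls at 10 CPM or more. CEACAM1 had 33 counts in DMSO 0 Gy against 580, 593 and 1414 in DMSO 4 Gy, DZNep 0 Gy and DZNep 4 Gy. Its radiation ratio was 4.35 in DMSO and 1.44 in DZNep, so the size of its rise rests largely on 1 library.

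In total, 290 genes rose and 120 fell after radiation, of which 129 and 29 changed at least 2-fold, and 164 of the 410 were also called under DZNep. Rises made up 70.7% of the calls, and 56.9% under plain library size scaling and 57.2% with a 10 CPM filter. The counts depended on the model: without drug as a factor edgeR's quasi-likelihood test called 0 genes (524 at an unadjusted p under 0.05), whereas DESeq2 with both factors called 447 and 214.

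Of 39 p53 targets, 24 rose after radiation and 0 fell (35 and 0 adjusted over the list alone), with a median of 1.05 against -0.13 to 0.12 for random lists. Of 37 S phase and replication genes, 0 rose and 14 fell (0 and 29 adjusted over the list alone; median -0.64). Of 36 mitosis genes 6 fell (13 adjusted over the list alone; median -0.41, with -0.79 in DMSO and, inside the range of random lists, -0.04 in DZNep), including CCNA2, KIF11 (-0.95, SE 0.20), ANLN (-0.85, SE 0.15) and AURKB (-0.82, SE 0.20). Of 40 double strand break repair genes 2 fell, EXO1 (-0.91, SE 0.15) and XRCC4 (-1.59, SE 0.34) (9 adjusted over the list alone). Of 24 MYC and ribosome biogenesis genes 1 fell, NPM1 by 0.52 (SE 0.12) (9 adjusted over the list alone). Of 31 inflammatory factors 6 rose (9 adjusted over the list alone), including ICAM1 (0.93, SE 0.17), TNFAIP3 (0.79, SE 0.14) and PLAU (0.79, SE 0.15). Of 30 stress response genes 4 rose (4, with 1 fall, adjusted over the list alone): SESN2 (1.31, SE 0.19), PPP1R15A (1.29, SE 0.20), ATF3 (0.9999, SE 0.18) and DDIT3 (0.86, SE 0.20). SESN2 is also in the p53 list.

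Other lists held few radiation calls. Cholesterol synthesis had TM7SF2 rising (1.27, SE 0.24) and 3 of 24 falling, INSIG1, SQLE (-0.92, SE 0.23) and STARD4 (-0.69, SE 0.15) (1 and 6 adjusted over the list alone). Apoptosis had 2 rises and 1 fall of 25 (2 and 2 adjusted over the list alone), with BAX at 0.93 (SE 0.17), BBC3 at 2.07 (SE 0.29) and CYCS at -0.82 (SE 0.16). BAX and BBC3 are also in the p53 list. Lysosome and autophagy had 2 rises of 28, ULK1 (0.90, SE 0.15) and GRN (0.77, SE 0.16) (3 adjusted over the list alone). Developmental regulators had 2 rises of 29, DLX2 (1.12, SE 0.25) and PAX7 (1.004, SE 0.17) (5 adjusted over the list alone). The genes linked to DZNep in earlier work had 3 rises of 9, CDKN1A, TXNIP and TGFBI (0.62, SE 0.14) (6 and 1 adjusted over the list alone). CDKN1A is also in the p53 list. Single calls were TGFBI among 29 epithelial and mesenchymal markers (5 adjusted over the list alone), ALDH3A1 (1.11, SE 0.14) among 30 NRF2 targets (2 rises and 5 falls adjusted over the list alone), KDM6B (0.82, SE 0.17) among 20 demethylases (1), ODC1 (-0.60, SE 0.14) among 26 methionine and polyamine genes (1 rise and 2 falls) and ACTA2 among 8 markers of other cell types (3 rises). The lists of Polycomb subunits, methyltransferases, interferon response, hypoxia and glycolysis, histones, germline genes, ribosomal proteins, neuroendocrine and lung lineage, and antigen presentation held 0 calls, and adjusted over the list alone only the last pair held any, with 1 rise each.

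In the 2-library ratios at 10 CPM or more, 167 genes were at least 2-fold higher and 80 lower at 4 Gy in DMSO, and 68 and 16 in DZNep. The spread of the ratios (SD across genes) was 0.455 in DMSO and 0.360 in DZNep, and both sets correlated across 8502 genes at r = 0.54 (rho = 0.51). Highest in DMSO were NLRP1 (3.79, interval 3.52 to 4.13), SULF2 (2.92), SPATA18 (2.91), ACTA2 (2.86) and ANK1 (2.81). Lowest in DMSO were MYO1G (-8.24, 5 against 2530 counts), CCNA2 (-1.63), LRR1 (-1.62), CLSPN (-1.59) and INSIG1 (-1.54). Highest in DZNep were PVT1 (4.31, interval 4.21 to 4.41), DENND4C (3.33), GDF15 (3.08), BTG2 (2.76) and FDXR (2.42). Lowest in DZNep were UNG (-1.64), DNAJC25 (-1.47), WDR76 (-1.38), RAB27A (-1.37) and CRLS1 (-1.37). DENND4C had 1932 counts in DZNep 0 Gy against 17082, 18973 and 13150 in DZNep 4 Gy, DMSO 0 Gy and DMSO 4 Gy, so its ratios rest on 1 library. It also lies tail to tail with RPS6, so its count is uncertain.

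**Figure D2:**
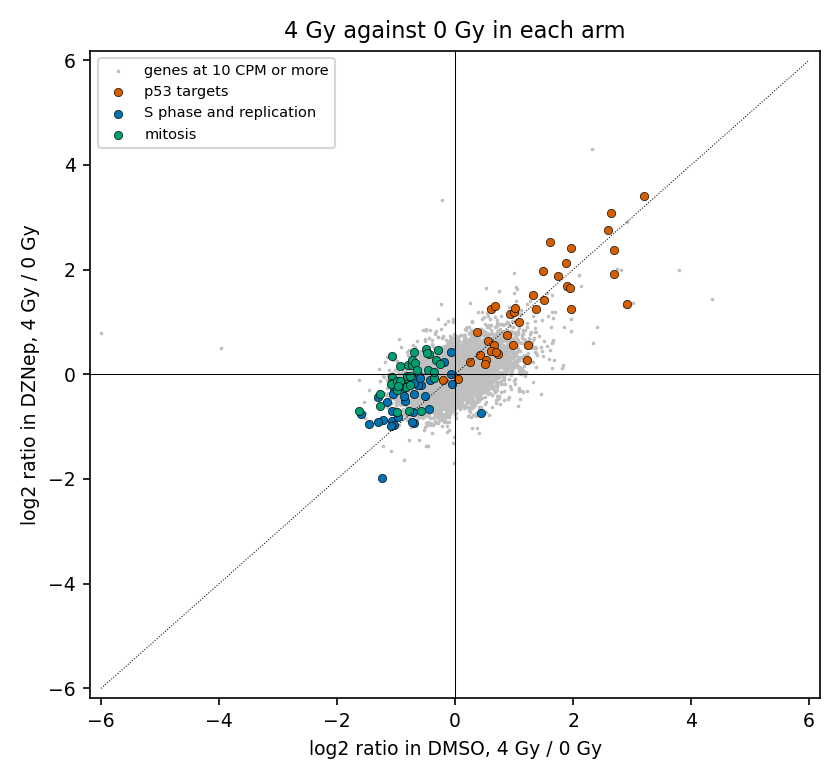
Log2 ratio of 4 Gy to 0 Gy in DMSO (x axis) and in DZNep (y axis), 1 library against 1, with each grey point a gene at 10 CPM or more, colours marking 3 gene lists, the dotted line equality, and 1 gene beyond 6 drawn at the edge. The p53 targets lie mostly above 0 on both axes (medians 1.08 and 1.25), and the mitosis genes have medians of -0.79 in DMSO and -0.04 in DZNep.

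Whether radiation acted differently with the drug could not be tested, because the interaction has no error estimate. Its value was at least 1 (2-fold) for 76 genes and at most -1 for 91. The highest at 10 CPM or more were MYO1G (9.02), CR1 (4.48), DENND4C (3.56), PVT1 (1.98) and IQCH-AS1 (1.64), and the lowest CEACAM1 (-2.91), ATP8B4 (-1.81), NLRP1 (-1.79), PCDH15 (-1.74) and STRA6 (-1.69). The value of CEACAM1 rests largely on its 33 counts in DMSO 0 Gy. PVT1 went from 6.03 to 30.3 CPM with radiation in DMSO and from 6.61 to 131 CPM in DZNep. Median interactions above the middle 95% of random lists were those of mitosis genes (0.77), S phase genes (0.38), cholesterol synthesis (0.38), ribosomal proteins (0.33), MYC and ribosome biogenesis (0.33), double strand break repair (0.26) and methyltransferases (0.21). Medians below it were those of genes linked to DZNep in earlier work (-0.33), the interferon response (-0.27) and lysosome and autophagy (-0.16), while p53 targets (-0.08) lay within it.

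**Figure D3:**
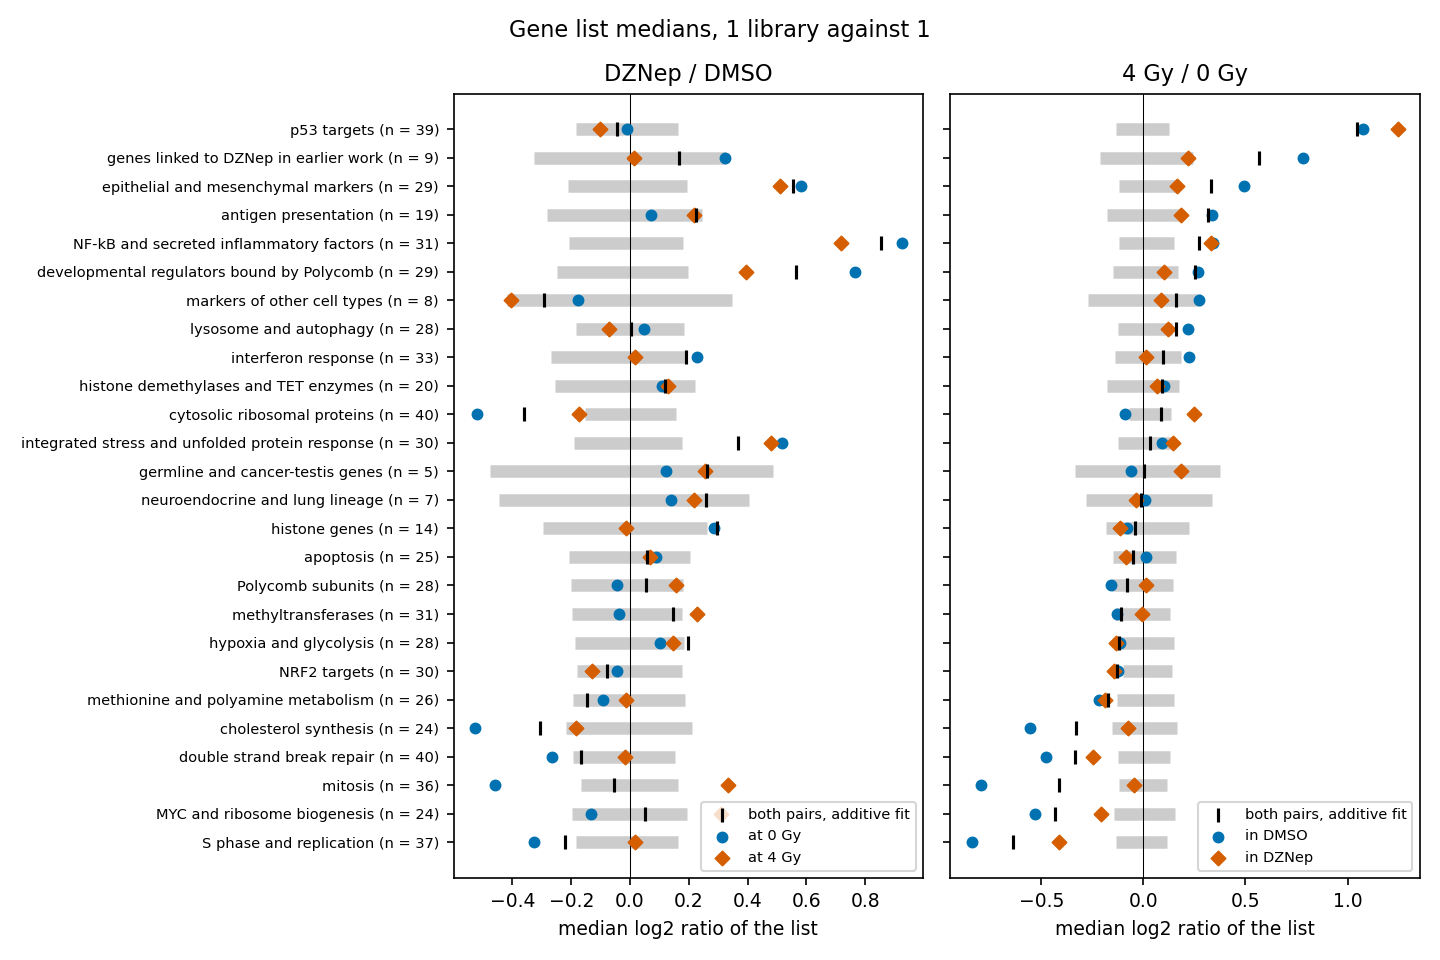
Median log2 ratio of each of 26 gene lists (n measured genes) for DZNep against DMSO (left) and 4 Gy against 0 Gy (right); circles and diamonds are the 2-library ratios, vertical ticks the additive model, and grey bars the middle 95% of random expression-matched lists for the ticks. The p53 targets have the highest radiation median (1.05) and S phase genes the lowest (-0.64).

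Cells given both treatments, compared with those given neither, had 491 genes at least 2-fold higher and 380 lower. The highest ratios at 10 CPM or more were those of CEACAM1 (5.61, interval 5.21 to 6.25), NUPR1 (5.28, interval 4.98 to 5.69), GDF15 (4.88), TNS4 (4.49) and PVT1 (4.44). The lowest were those of AKR1B15 (-4.17), LOC388282 (-3.92), MYO1G (-3.72), KMO (-3.58) and FAM19A5 (-3.28). CEACAM1, GDF15 and NUPR1 were higher with each treatment alone too. With radiation the ratios were 4.35, 2.64 and 3.01, and with DZNep 4.17, 1.80 and 3.91. These ratios and those of both treatments share the DMSO 0 Gy library, so they are not independent. CEACAM1 had 33 counts there and NUPR1 had 70. In the pairs without that library, radiation in DZNep gave 1.44 for CEACAM1, 3.08 for GDF15 and 1.37 for NUPR1. DZNep at 4 Gy gave 1.265, 2.23 and 2.26.

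**Figure D4:**
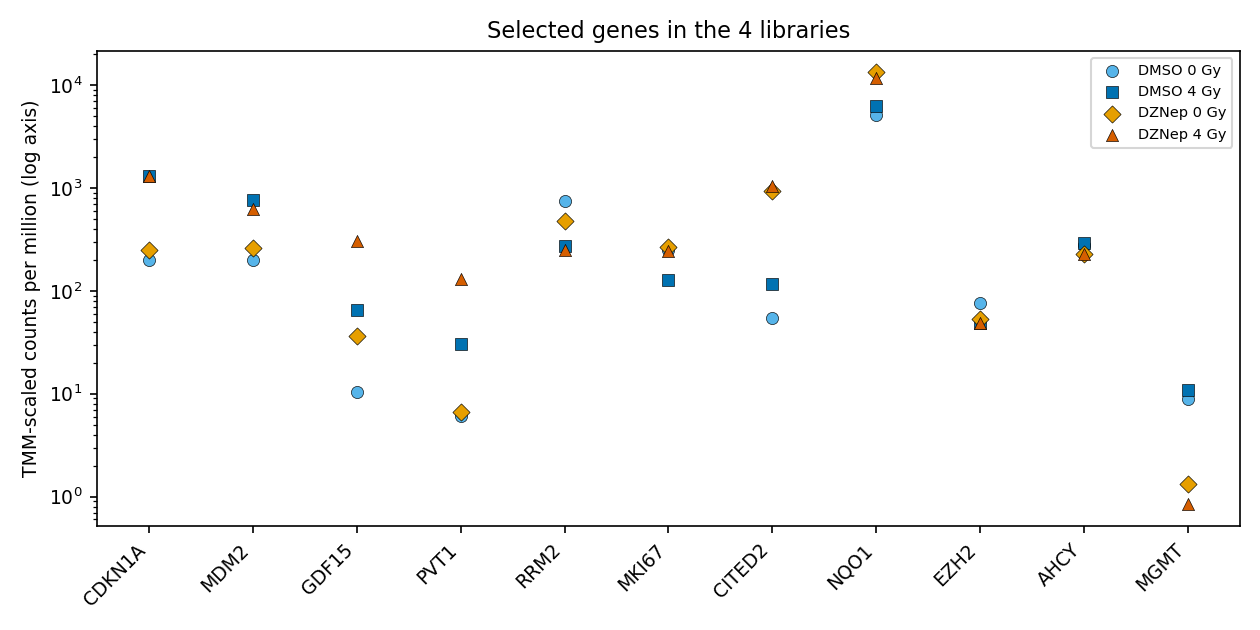
TMM-scaled CPM (log axis) of 11 genes in the 4 libraries, 1 marker per library. CDKN1A lies at 1296 and 1307 CPM in the irradiated libraries, and CITED2 lies at 945 and 1034 CPM in both DZNep libraries against 54.97 and 117 CPM in DMSO.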

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

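The test for 1 library out of place was chosen after the result was seen, as were setting the scaling test beside random lists and the use of random lists to judge opposite list medians; the GC and length test was written before its result. Among 214 named genes and 26 lists, 20 results had opposite directions in the arms or at the doses compared. For genes both ratios were beyond 0.333, the SD that the model implies for 1 gene's 2-library log2 ratio, and for lists both medians were outside the middle 95% of random lists. None of these differences was tested, and 7 of them belong to genes named for a large interaction.

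Radiation ratios had opposite signs in the drug arms for 11 genes. MYO1G was at 0.79 in DZNep and -8.24 in DMSO, CR1 at 0.51 and -3.97, IRF7 at 0.34 and -1.15, IQCH-AS1 at 0.68 and -0.96, UBE2C at 0.42 and -0.47, and DNMT3B at 0.43 and -0.56. The other way round, NRAP was at -0.47 in DZNep and 1.09 in DMSO, ZSCAN31 at -0.36 and 0.59, ATP8B4 at -0.37 and 1.45, CTH at -0.34 and 0.78, and HIST1H1C at -0.60 and 1.06. MYO1G had 2530 counts in DMSO 0 Gy and 5, 102 and 156 in the other libraries.

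DZNep ratios had opposite signs at the doses for 8 genes and 1 list. CCNA2 was at 0.49 at 4 Gy and -0.45 at 0 Gy, MYO1G at 4.51 and -4.51, DENND4C at 0.36 and -3.20, AURKB at 0.50 and -0.41, BARD1 at 0.47 and -0.64, and H2AFV at 0.72 and -0.48. SULF2 was at -1.04 at 4 Gy and 0.58 at 0 Gy, and STRA6 at -0.82 and 0.87. The mitosis list had a median of 0.33 at 4 Gy (random lists -0.15 to 0.20) and -0.46 at 0 Gy (random lists -0.19 to 0.15).

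Mitosis genes had a median radiation ratio of -0.79 in DMSO and -0.04 in DZNep, an interaction median of 0.77. After trends with GC content and gene length were removed the median was 0.85, which speaks against such a trend as the cause, above -0.11 to 0.15 for random lists. A factor common to all genes of a library moves them alike. The list stood 0.77 above the median of all tested genes under TMM, RLE and plain library size. This is the same number by construction, so comparing these scalings decides nothing, and other scaling errors were not tested. Relative to their mean over libraries the genes lay at 0.41 in DMSO 0 Gy, -0.36 in DMSO 4 Gy, 0.02 in DZNep 0 Gy and -0.05 in DZNep 4 Gy, so DMSO 0 Gy was 0.46 and DMSO 4 Gy -0.38 from the median of the others. With 1 library per group, an aberrant library in either DMSO group, a different density or cycle stage of 1 culture, and a drug that alters the mitotic response to radiation cannot be told apart, and the last may be the case only as a hypothesis.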

How the results depend on the processing

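Thinning to 50% and leaving out short RNA symbols were chosen after the data were examined. Over all alternatives, 1694 named-gene values kept their direction and side of the threshold, 94 newly passed it, 130 no longer did and 6 changed sign; 191 list medians moved by less than 0.1 and 17 by more. Of the counts and correlations, 107 stayed within their tolerance and 45 did not. With all counts thinned to 50%, DZNep calls numbered 3058 in place of 3086 and radiation calls 523 in place of 410.

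DZNep calls (1446 higher, 1640 lower) became 355 and 366 without dose in the model, 722 and 779 at an adjusted p of 0.01, and 553 and 693 with a 2-fold minimum. Radiation calls (290 and 120) became 0 and 0 without drug in the model, 447 and 214 with DESeq2, 134 and 65 without a filter, 590 and 441 with a 10 CPM filter, 70 and 13 at an adjusted p of 0.01, and 129 and 29 with a 2-fold minimum; plain library size gave 266 falls. Without the other factor its effect counts as spread, and stricter thresholds keep fewer genes by construction; for the other settings the cause was not tested. All 721 DZNep calls without dose, and 398 of the 661 DESeq2 radiation calls, were among the calls reported.

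With no minimum CPM and with 50 CPM, genes 2-fold higher and lower numbered 733 and 785, and 125 and 81, for DZNep at 0 Gy; 630 and 856, and 97 and 86, for DZNep at 4 Gy. For radiation they were 482 and 208, and 51 and 26, in DMSO, and 243 and 147, and 19 and 2, in DZNep, where plain library size gave 27 lower. For both treatments they were 1027 and 888, and 205 and 117, and for the interaction 263 and 431, and 17 and 15. The minimum sets how many genes enter, so the shifts between minimums follow from it. For the shift under plain library size the cause was not tested. The correlation of radiation ratios was 0.41 with no minimum, and ranged from 0.41 to 0.59 over all settings, that of DZNep ratios from 0.73 to 0.78.

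Named-gene values that changed sign were near 0 and far from the threshold: MDM2 under DZNep was -0.14 without dose in the model (0.041 as reported), MAGEB2 under radiation was -0.028 with plain library size, -0.0029 without a filter and -0.021 after thinning (0.0046 as reported), and UCHL1 under radiation was 0.00082 with DESeq2 and 0.00082 with RLE (-0.012 as reported). The cause was not tested. Among the 17 list medians that moved, markers of other cell types under DZNep went from -0.29 to 0.28 without a filter, germline genes under radiation from 0.0046 to -0.12 without a filter, and neuroendocrine and lung lineage genes under radiation from -0.012 to 0.32 without a filter and 0.11 with a 10 CPM filter. The filter sets which members of these short lists enter.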

Other observations

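The gene families here, the test for 1 shared protocadherin count and the reading of the beta cluster and scaling tests were chosen after the results were seen. Of 41 families scanned under 3 effects, 60 of 123 medians lay outside the middle 95% of random lists, so standing outside is weak evidence.

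Immediate early genes, listed after several had been seen among the top rises, moved upward with DZNep: 25 of 36 rose and 1 fell (median 1.11, and 1.04 after GC and length trends were removed). NR4A1, an orphan nuclear receptor, stood at 1902 and 1666 CPM with DZNep against 295 and 509 CPM in DMSO (2.20, SE 0.20), and RGS2 rose by 2.18 (SE 0.20), while EGR1 fell by 1.49 (SE 0.25). Among FOS and JUN genes of the list, FOSB (1.55, SE 0.41) and JUNB (1.59, SE 0.17) rose. FOS (0.49, SE 0.24), FOSL1 (0.29, SE 0.14), JUN (0.02, SE 0.26) and JUND (-0.46, SE 0.21) did not pass the test. Of 9 keratin genes 6 rose and 1 fell (median 1.35), with KRT8 at 1.35 (SE 0.13) and KRT18 at 1.58 (SE 0.13), though KRT81 and KRT86 resemble each other closely and their counts are uncertain. Of 23 HOX genes 10 rose, HOXC10 by 1.60 (SE 0.29) and HOXA7 by 1.496 (SE 0.26), and 3 fell, HOXA2 by 2.43 (SE 0.34).

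For other families the ratios of single libraries are given, and no difference between arms was tested. Genes with symbols starting TUB had a median ratio of -0.50 in DMSO and 0.17 in DZNep over 21 genes (interaction 0.67). Besides tubulins, these include the gamma-tubulin complex genes TUBGCP2, TUBGCP3, TUBGCP4, TUBGCP5 and TUBGCP6. Mitochondrial ribosomal protein genes had -0.35 and -0.03 over 79 genes (interaction 0.26), and proteasome subunits -0.38 and -0.08 over 41 genes (interaction 0.26). Under radiation the additive model called 0 of the last pair of families in either direction. Aminoacyl-tRNA synthetase genes had 5 rises and 1 fall of 20 with DZNep, YARS by 0.92 (SE 0.17). ZNF genes had 17 rises and 29 falls of 328.

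Ribosomal protein genes had a median of -0.36 with DZNep, and 13 of 40 fell. After GC and length trends were removed the median was -0.33, below -0.15 to 0.15 for random lists, which speaks against such a trend as the whole cause. The list lay -0.35 from the median of all tested genes, and random lists lay between -0.14 and 0.17. That distance is the same under TMM, RLE and plain library size by construction, so comparing these scalings decides nothing. A factor common to all genes of a library would not give such a distance, and other scaling errors were not tested. The median was -0.52 at 0 Gy and -0.17 at 4 Gy. An effect of the drug and a difference between cultures or libraries both stay open, since each group has 1 library and neither was tested apart from the other.

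Of 41 measured clustered protocadherin genes, which encode cell adhesion proteins, 30 fell with DZNep (median -0.67), all of them among the 37 genes of the alpha and gamma clusters, whose members share exons. The median was -0.77 after GC and length trends were removed, below -0.22 to 0.17 for random lists. The 4 beta cluster genes, which share no exon, had a median of 0.17, but random lists of that size reached -0.84, so this decides nothing; it was first read as favouring shared exons. The ratio of the largest to the smallest member count (median 2.04 over clusters and libraries, range 1.20 to 6.96) is set by a few members and decides nothing either: in DMSO 4 Gy the 13 alpha genes had a minimum of 181 counts, held by 6 of them, a median of 183 and a maximum of 617, and in DMSO 0 Gy the 12 gamma A genes had 4186, 4395 and 8677. Most members thus held nearly the same count, as reads of common exons counted for each member would give, so the 30 falls may stand for few independent ones. PCDHA2, PCDHA3, PCDHA4, PCDHA5, PCDHA7 and PCDHA8 each held 181 counts in DMSO 4 Gy and 194 to 200 in DMSO 0 Gy. With DZNep they held 84 to 86 at 0 Gy and 51 to 55 at 4 Gy. Such a match argues against separately measured falls of these genes. Without reads per exon, which members fell, and whether many did, cannot be told.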
